A study of Homo sapiens with 4 samples.

How the data were processed

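Total RNA of HepG2 cells, a line derived from a human liver cancer that keeps many hepatocyte features, was measured on the U133 Plus 2.0 array of Affymetrix, which reads each transcript with 1 or more probe sets. There were 4 arrays, 1 for each of 0, 2, 6 and 12 h of treatment with 200 ng/ml APRIL, a secreted ligand of the tumour necrosis factor family. The cells had been without serum for 24 h per the series' design text, and overnight per the labels' protocols. The 0 h array was the only untreated one among the arrays used here.

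The deposited table held log2 values for 54675 probe sets, made with RMA per the submitters' processing notes, where no version is given. RMA corrects background, equalises the distributions of the arrays and summarises the probes of each set. In the deposited log2 values the median of each probe set over the 4 arrays was 0 within 1e-06, so each value is relative to the probe set's own median and no expression level is left. The software that centred the values is not given in the sources used here. Base 2 was taken because RMA works on that scale, and a higher value was taken as more transcript. Neither the base nor the direction is stated, and no scanner files were used here that could test them. The median of each column was -0.0050 at 0 h, 0 at 2 h, 0.011 at 6 h and -0.0043 at 12 h.

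Gene symbols came from the platform annotation, updated through the gene identifier to the RefSeq annotation of the GRCh38.p14 assembly. This assembly was used for names and gene classes only. Of the probe sets, 41091 had 1 symbol, 1801 had several, 11721 had no gene name in this annotation and 62 were Affymetrix controls. Only those with 1 symbol were used for genes, of which there were 19775, and 10523 of these had 2 or more probe sets.

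The log2 ratio between pairs of arrays was computed per probe set, and a gene's ratio was the median over its probe sets, taken separately in each comparison. Genes at or past 2-fold (a log2 ratio of 1) were counted in each direction. With 1 array per time there is no replicate error and no test, so no p-value is given, and every difference is a difference between 2 arrays. As yardsticks, the SD between a gene's probe sets is given for some of the genes that have several, and the spread of all genes between the 0 h and 2 h arrays (a robust SD of 0.16) is used. A gene printed without an SD may still have several probe sets. The first covers measurement within these arrays only. The second also holds any difference between these 2 samples, a response at 2 h included. Neither measures variation between replicate cultures. The small number of arrays limits the precision of every value.

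Before the data were examined, 29 gene lists were fixed, with 486 entries of which 434 could be read here. The other entries are not analysed here. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, and a list is said to stand apart below percentile 0.5 or above percentile 99.5. With 87 combinations of list and time, 0.87 would be expected outside by chance. Percentiles describe these arrays only. They are too extreme for lists whose genes vary together, because random genes do not. Random lists were also drawn from all genes without regard to expression level. If genes of low level vary less between arrays, percentiles are too extreme for lists of expressed genes. Without levels this could not be checked. The genes named were also chosen by a rule fixed before the data were examined. For each time these were the 12 highest and 12 lowest genes past 2-fold whose probe sets all had 1 sign (at least 5 in each direction, if need be below 2-fold), the 4 members with the largest ratios of each list that stood apart and of 6 lists in any case (NF-kB, immediate-early, APRIL system, acute-phase, G1/S and G2/M), and the 10 largest of the genes past 2-fold at all 3 times.

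Some planned steps needed an expression level, which the centred values do not hold. A floor on dim probe sets, the brightest probe set per gene and random lists matched on mean expression could not be used. The median over probe sets, planned as an alternative, took the place of the brightest, and random lists were matched on the number of probe sets (1, 2, or 3 and more). Alternatives were centring each array on its median, leaving out probe sets whose names end in _x_at or _s_at (which can match several transcripts), thresholds of 1.5-fold and 3-fold, and the mean of the other 3 arrays as the reference. Alternatives chosen after seeing the data were the probe set with the widest range per gene and centring on the bacterial spike-in probe sets.

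The computation was tested on simulated data in which 200 of 19775 genes were changed in the 12 h over 0 h comparison, 50 at each size. It recovered 36% of genes changed by exactly 2-fold and 100% of those changed by 3-fold, and placed 6 of 19575 unchanged genes past 2-fold. Among unchanged lists, 1.26% of comparisons fell outside the percentile range. The simulated noise came from the 2 h over 0 h ratios, drawn separately for each probe set. The robust SD over genes was 0.16 in that comparison and 0.24 for 12 h over 0 h. These figures therefore check the computation and do not give the number of false calls at 12 h. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.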

Results

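Gene expression was measured in serum-starved HepG2 cells on 4 arrays, 1 each at 0, 2, 6 and 12 h of treatment with 200 ng/ml APRIL. The series asks how gene expression changes over this time course. Each time was compared with 0 h, and successive times with each other. All values are log2 ratios between 2 arrays, with no replicates and no time-matched untreated array, so neither culture variation nor an effect of time alone is separated from the treatment. The spread of all 19775 genes, as an SD, was 0.19 for 2 h over 0 h, 0.24 for 6 h over 0 h and 0.35 for 12 h over 0 h. The number of genes at or past 2-fold was 7 higher and 2 lower at 2 h, 20 higher and 56 lower at 6 h, and 187 higher and 195 lower at 12 h.

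**Figure D1:**
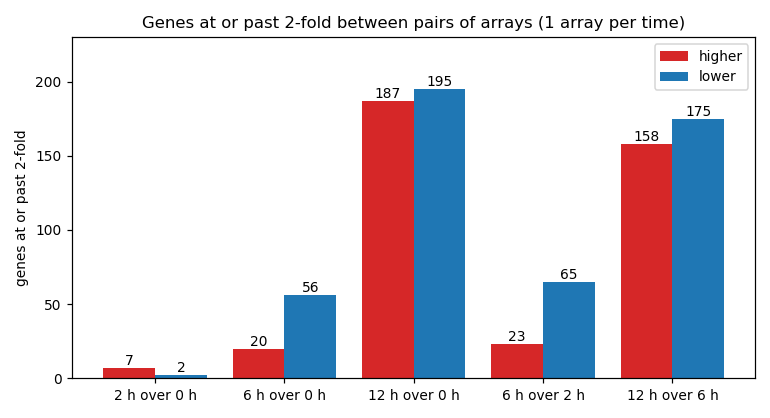
The bars give the number of genes at or past 2-fold higher (red) or lower (blue) for each pair of arrays, with 1 array per time and no error. The 12 h array gave 187 higher and 195 lower genes against 0 h, and the 2 h array gave 7 and 2.

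At 2 h, all genes past 2-fold upward were metallothioneins, the small cysteine-rich proteins that bind zinc and copper. MT1M was highest, with a log2 ratio of 2.03 (4.09-fold). It was followed by MT1X at 1.64 (SD 0.069 over 2 probe sets), MT1E at 1.58 (SD 0.030 over 2 probe sets), MT2A at 1.505, MT1H at 1.46, MT1F at 1.38 and MT1HL1 at 1.27. The list of 7 metallothioneins had a median of 1.505, above all 10000 random lists. Of its members 6 were past 2-fold, and MT1G lay at 0.85, with its 2 probe sets in opposite directions (SD 1.25). Of the 7 genes past 2-fold all but MT1M are read only by probe sets that can match several transcripts, so they are not separate readings. Without such probe sets 2 genes were past 2-fold higher, of which only MT1M was among the 7. The genes lower by 2-fold or more were H3C2, a replication-dependent histone gene, at -1.28, and LY86, an accessory protein of innate immune receptors, at -1.11. Next, below 2-fold, came MATN3 at -0.89, GMNC at -0.85 and LOC339685 at -0.85. Each of these 5 rests on 1 probe set. Against the mean of the other 3 arrays H3C2 was at -0.15 and LY86 at -0.89, so both calls ended, and H3C2 has no value without the probe sets that can match several transcripts.

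Beyond the metallothioneins, 2 more lists stood apart at 2 h, both with small shifts. The ER stress and amino acid response list had a median of 0.21 over 20 genes (above all random lists), with 16 members above 0 and none past 2-fold. Its largest members were SDF2L1 at 0.54, TRIB3 at 0.48, SLC7A11, the cystine transporter, at 0.47 and PHGDH, the first enzyme of serine synthesis, at 0.45. The G1/S and DNA replication list had a median of -0.11 over 21 genes (percentile 0.25), with 17 members below 0 and none past 2-fold. UHRF1 was at -0.37, ORC1 at -0.36, MCM10 at -0.30 and GINS2 at -0.28. Without the probe sets that can match several transcripts, the medians of 0.14 and -0.12 no longer stood apart. Against the mean of the other 3 arrays the ER stress list, at 0.11, no longer stood apart and the replication list was at 0.22. That mean holds the 12 h array, where the first list was high and the second low, so both move this way by arithmetic.

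Of the lists that describe early signalling, none stood apart at 2 h. The immediate-early list, 19 genes with FOS, JUN and EGR1 among them, had a median of 0.05 (percentile 74.97), with FOS at -0.49, IER2 at 0.34, ZFP36 at 0.31 and MYC at 0.23. The NF-kB target list had a median of 0.02 over 20 genes, 10 above and 10 below 0, with ICAM1 at 0.40, TNFAIP2 at -0.40, RELB at 0.37 and CFB at 0.34. The acute-phase list, 16 liver plasma proteins and their regulators, had a median of 0.07, with HAMP (hepcidin) at 0.41, HPX at -0.24, SOCS3 at 0.22 and FGA at 0.20. The G2/M list had a median of -0.05 over 20 genes, with TTK at -0.34, CDC20 at 0.31, TOP2A at -0.25 and BUB1 at -0.20. In the list of APRIL and related ligands, receptors and adaptors the median was 0.04 over 14 genes. TNFRSF17, the receptor BCMA, was at 0.27, TNFRSF13C at -0.25, TNFSF13, APRIL itself, at 0.24 and TRAF5 at 0.18.

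At 6 h the metallothioneins were still higher than at 0 h, with a median of 1.25 and 6 of 7 past 2-fold. MT1M was at 1.33, MT2A at 1.31, MT1F at 1.31 (SD 0.054 over 2 probe sets), MT1H at 1.25 and MT1X at 1.13. The highest genes were RAD54B, a homologous recombination gene, at 1.76, IFIT1, an interferon-stimulated gene, at 1.501, the folate receptor FOLR1 at 1.477, CYP7A1, the rate-limiting enzyme of bile acid synthesis, at 1.38 and DEPDC7 at 1.34. HSPH1, a heat-shock chaperone, was at 1.12 (SD 0.13 over 3 probe sets) and RSRP1 at 1.09. RAD54B, IFIT1, CYP7A1 and DEPDC7 rest on 1 probe set each, and the probe sets of FOLR1 were far apart (SD 1.42 over 2). The interferon-stimulated list as a whole had a median of 0.02 over 17 genes (percentile 30.2), with IFIT1 its only member past 2-fold.

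The lowest gene at 6 h was MALAT1, a nuclear noncoding RNA, at -2.09 (SD 0.87 over 12 probe sets). The histone genes H1-4 and H3C2 were at -1.76 and -1.59, the ribosomal RNA precursor RNA45SN5 at -1.51, and the antisense transcripts ENO1-AS1 and ST7-AS1 at -1.51 and -1.48. The phosphate transporter SLC20A1 was at -1.67, the intraflagellar transport genes IFT70B and IFT70A at -1.66 and -1.43, and ARRDC4 at -1.65. APOB, the structural protein of low-density lipoprotein, was at -1.60 and SLC7A11 at -1.50 (SD 0.24 over 3 probe sets). Probe sets of APOB (SD 1.98 over 2) and SLC20A1 (SD 1.56 over 2) disagreed widely in size. H1-4, H3C2, ARRDC4, ENO1-AS1, ST7-AS1 and IFT70A rest on 1 probe set each. IFT70A and IFT70B are close copies whose probes may not tell them apart, and histone genes are likewise similar in sequence. At the level of genes, 15 of 2656 lncRNA genes (0.565%) and 37 of 16516 protein-coding genes (0.224%) were past 2-fold lower at 6 h. At 12 h the order was the other way, with 0.527% and 1.07%.

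At 6 h, 6 lists stood apart. The heat-shock list had a median of 0.41 over 9 genes, above all random lists, with 8 members above 0. After HSPH1 came DNAJA1 at 0.80, DNAJB1 at 0.65 and HSPA4L at 0.53. The G2/M and mitosis list had a median of 0.21 over 20 genes (percentile 99.96), with 16 above 0 and none past 2-fold. The spindle checkpoint kinase TTK was at 0.75, AURKA at 0.69, CENPE at 0.62 and KIF20A at 0.51. On the lower side, the WNT target list was at -0.17 (14 genes, 12 below 0, percentile 0.060), with DKK1 at -0.59, NKD1 at -0.56, and MYC and LGR5 both at -0.37. The hypoxia and glycolysis list was at -0.14 (18 genes, 11 below 0, percentile 0.060), with BNIP3L at -0.82, PDK1 at -0.70, HK2 at -0.55 and EGLN3 at -0.51. The TGF-beta and BMP list was at -0.13 (16 genes, 11 below 0, percentile 0.22), with HAMP at -1.16, ID2 at -0.82, ID1 at -0.35 and KLF10 at -0.31. Without the probe sets that can match several transcripts, 4 of the 6 no longer stood apart: metallothioneins at 0.54, G2/M at 0.17, hypoxia at -0.18 and TGF-beta at 0.03. The hypoxia median was not smaller in size. Random lists are drawn anew from the gene values of each setting, so a call can end without a smaller shift.

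The immediate-early, NF-kB, acute-phase, replication and APRIL system lists did not stand apart at 6 h. The immediate-early list had a median of 0.00 (percentile 18.3), with ZFP36 at 0.59, DUSP1 at 0.43, CCN2 at -0.40 and MYC at -0.37. The NF-kB list was at 0.03 (percentile 34.2), with CFB at 0.49, IER3 at 0.41, IL6 at 0.40 and CXCL8 at 0.34. The acute-phase list was at 0.07, with HAMP as given above, CP (ceruloplasmin) at -0.30, HP (haptoglobin) at 0.30 and CRP at 0.27. The replication list was at -0.01 (percentile 12.9), with CCNE2 at -0.34, SLBP at -0.32, ORC1 at 0.26 and MCM3 at 0.21. The APRIL system list was at 0.11, with GPC3 at -0.54, JUN at 0.29, TNFRSF13C at 0.26 and TNFSF13 at 0.25.

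At 12 h the metallothioneins lay far below the 0 h array. Their median was -2.56, below all random lists, with all 7 below 0 and 6 past 2-fold. MT1X was at -3.07 (SD 0.21 over 2 probe sets), MT1E at -3.05 (SD 0.30 over 2), MT1H at -2.79, MT2A at -2.56, MT1HL1 at -2.45 and MT1F at -2.31, and MT1M at -0.48. MT1HL1 is not on the list. MT1G, which is, was at -1.48, but its 2 probe sets disagreed, at -2.85 and -0.11. Between 6 h and 12 h the list median was -3.87, with all 7 genes past 2-fold lower. For MT1G this call did not hold in both probe sets, since the second was at -0.25 at 6 h and -0.11 at 12 h against 0 h. Metallothionein sequences are alike, and of the probe sets behind these genes all but those of MT1M and one of MT1G can match several transcripts. With those left out, MT1M and MT1G alone gave medians of 0.54 at 6 h and -0.30 at 12 h, and neither stood apart.

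DNA replication genes were lower at 12 h. The G1/S and replication list had a median of -0.95, below all random lists, with 21 of 21 members below 0 and 9 past 2-fold. UHRF1, which couples DNA methylation to replication, was at -2.11, RRM2, a ribonucleotide reductase subunit, at -1.91 (SD 0.14 over 2 probe sets), MCM10 at -1.83 (SD 0.49 over 3) and the helicase subunit MCM6 at -1.57 (SD 0.22 over 2). Against 6 h the list median was -1.005, with 11 genes past 2-fold lower. The G2/M list was also lower, with a median of -0.27 over 20 genes and 15 below 0, none past 2-fold, and CCNA2 at -0.77, TOP2A at -0.72, CDK1 at -0.62 and BIRC5 at -0.53. Against 6 h all 20 were lower, with a median of -0.48. Centred on the bacterial spike-in RNAs, the replication list stayed lower than at 0 h and the G2/M list was at 0.08. That centring raises every 12 h ratio alike, so it leaves the place of each list among random lists unchanged.

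Lipid synthesis genes were lower too. The cholesterol synthesis list had a median of -0.55 over 15 genes, below all random lists, with 13 below 0. HMGCS1, which makes the HMG-CoA for sterol synthesis, was at -1.36 (SD 0.26 over 2 probe sets), ACAT2 at -0.92, SQLE at -0.83 and FDPS at -0.81. The fatty acid synthesis list was at -0.24 (14 genes, 12 below 0, percentile 0.050), with SCD, the stearoyl-CoA desaturase, at -1.44, PNPLA3 at -1.14, ACSS2 at -0.73 and ACLY at -0.53. The hypoxia and glycolysis list was at -0.29 (18 genes, 13 below 0, below all random lists), with VEGFA at 1.01 against that direction, PDK1 at -0.92, PGK1 at -0.75 and BNIP3 at -0.71. Spike-in centring, which raises every 12 h ratio alike, turned the last of these lists to 0.06 and fatty acid synthesis to 0.11. Their places among random lists stay the same under it. Without the probe sets that can match several transcripts, fatty acid synthesis, at -0.19, no longer stood apart.

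Immediate-early and NF-kB genes were higher at 12 h. All 19 immediate-early genes were above 0, with a median of 0.52, above all random lists, and 5 were past 2-fold. The transcription factor EGR1 was at 2.91 (7.53-fold, SD 0.59 over 3 probe sets), the matricellular protein CCN1 at 2.00 (SD 0.13 over 2), JUN at 1.42 (SD 0.66 over 4) and ATF3 at 1.23 (SD 0.95 over 3, not all of 1 sign). The NF-kB list had a median of 0.35 over 20 genes, above all random lists, with 16 above 0 and 4 past 2-fold. These were the neutrophil chemokine CXCL8 (interleukin 8) at 2.56 (5.88-fold, SD 0.23 over 2 probe sets), IER3 at 1.98, the adhesion molecule ICAM1 at 1.31 (SD 0.55 over 3) and RELB, a NF-kB subunit, at 1.20. The ERK feedback list was at 0.32 (15 genes, 12 above 0, percentile 99.97), with IER3 as above, EPHA2 at 1.66, DUSP5 at 0.93 and SPRY4 at 0.80. The ER stress and amino acid list was at 0.61 (20 genes, 18 above 0, above all random lists), with PPP1R15A at 1.31, ATF3 as above, DDIT4 at 1.13 and DDIT3 at 0.99. The angiogenic and growth factor list was at 0.22 (18 genes, 13 above 0, percentile 99.87), with HBEGF at 1.28 (SD 1.20 over 4 probe sets), VEGFA at 1.01 (SD 0.21 over 4), PGF at 0.58 (SD 1.83 over 2) and EREG at 0.48 (SD 0.97 over 2), the last 2 with probe sets in opposite directions. With the probe set of widest range per gene the angiogenic list, at 0.24, no longer stood apart. Several genes belong to more than 1 of these lists.

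Among the single genes at 12 h the highest was SLC6A14, an amino acid transporter, at 3.29 (9.81-fold). SLC22A15 was at 2.70, UGT2B4, a glucuronosyltransferase acting on bile acids, at 2.36, the amino acid transporter SLC7A10 at 2.36, FILIP1L at 2.15 (SD 1.21 over 3 probe sets), SOX8 at 2.11, RBM24 at 2.03 and LDLRAD3 at 2.03. The lowest was ALDH8A1, an aldehyde dehydrogenase, at -3.23 (9.41-fold lower). SLC2A3, a glucose transporter, was at -2.75 (SD 0.35 over 3 probe sets), TMEM141 at -2.12, LOX, the lysyl oxidase, at -2.01 (SD 1.18 over 3) and BHMT, which remethylates homocysteine, at -1.97. SLC6A14, SLC22A15, UGT2B4, SLC7A10, SOX8, RBM24, LDLRAD3, ALDH8A1, TMEM141 and BHMT rest on 1 probe set each.

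Other lists did not stand apart at 12 h. The acute-phase list had a median of 0.10 (percentile 89.3) with members in both directions: HAMP at -1.13, ITIH3 at 1.03, SERPINA3 at 1.02 and CP at -0.97 (SD 0.82 over 4 probe sets, not all of 1 sign). The APRIL system list was at 0.18 (percentile 98.5), with JUN as above, GPC3, a heparan sulphate proteoglycan, at -0.72 (SD 1.40 over 2 probe sets in opposite directions), TRAF3 at 0.48 and TRAF6 at 0.36. The hepatocyte identity list was at -0.03, metabolic P450 and drug-metabolism genes at -0.05, fatty acid oxidation at -0.09, interferon-stimulated genes at 0.01, p53 targets at 0.01, apoptosis regulators at 0.11, FOXO and starvation genes at 0.07, TGF-beta and BMP targets at -0.05, WNT targets at 0.14, NRF2 targets at 0.02, heat-shock genes at 0.08, circadian genes at -0.06 and ribosomal proteins at 0.05. Without the probe sets that can match several transcripts, the FOXO and starvation list did stand apart at 12 h, at 0.28, and so did the NRF2 list at 2 h, at 0.19. Markers of other cell types were at -0.06 for immune cells, 0.10 for fibroblasts and -0.12 for endothelium, with none of their genes past 2-fold at any time against 0 h. Over all lists that did not stand apart, medians ranged from -0.10 to 0.12 at 2 h, from -0.08 to 0.13 at 6 h and from -0.12 to 0.18 at 12 h.

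**Figure D2:**
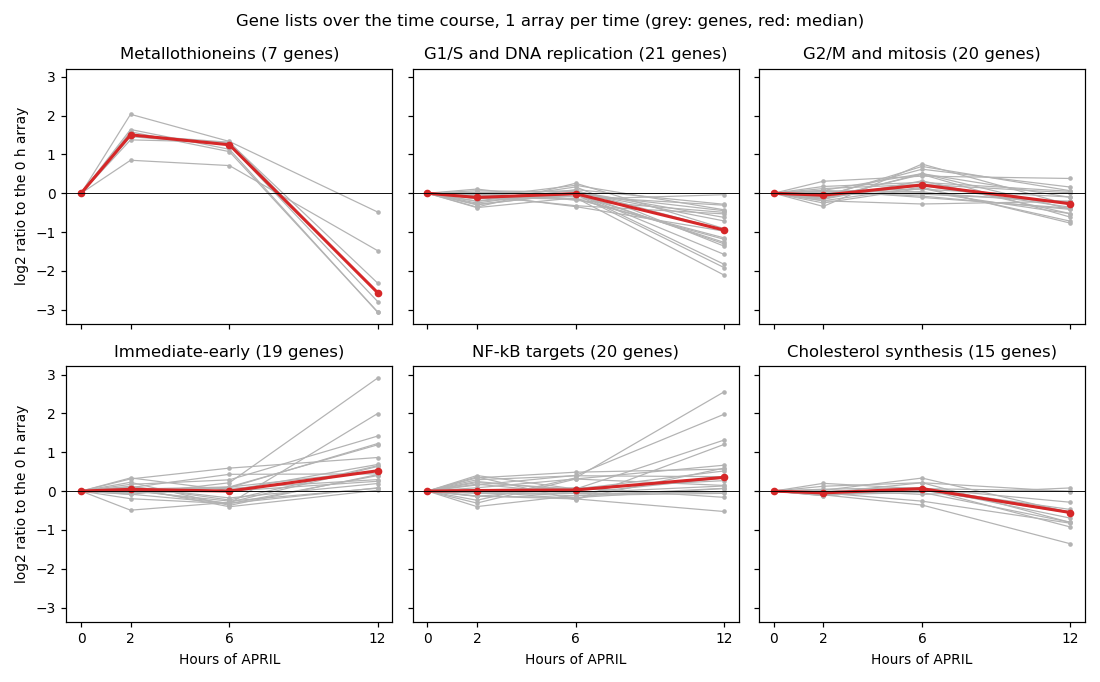
Each panel plots the log2 ratio to the 0 h array against hours of APRIL, with grey lines for the genes of 1 list and red for their median, 1 array per time and no error. The metallothionein median runs from 1.505 at 2 h to -2.56 at 12 h, and the replication median from -0.11 to -0.95, while immediate-early and NF-kB medians reach 0.52 and 0.35 at 12 h.

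The bacterial RNAs added at hybridization, read by 18 control probe sets, had a median log2 ratio of 0.01 at 2 h, 0.06 at 6 h and -0.35 at 12 h against 0 h, with all 18 lower at 12 h (from -0.47 to -0.21). The median of all genes was 0.02, 0.05 and 0.01 at these times. Relative to the spike-in RNAs every 12 h ratio is 0.35 higher, and the count at 12 h becomes 694 higher and 76 lower in place of 187 and 195. The 12 h directions above are therefore relative to the median gene of the array.

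The comparisons with 0 h share 1 array, whose chance values enter all 3. All 7 genes higher at 2 h were also higher at 6 h, where independent lists of these sizes would share 0.0071 genes and simulated unchanged arrays against 1 shared array share 1.86. These 7 are the metallothioneins, whose shared probe sets make them fewer than 7 separate readings, and without such probe sets 2 genes were shared. Between 6 h and 12 h, 4 genes were higher at both times (1.98 simulated, 0.19 independent) and 26 lower at both (1.97 simulated, 0.55 independent). The covariance of the log2 ratios of 6 h and 12 h was 0.033, against 0.017 simulated, that of 2 h and 12 h 0.019 against 0.017, and that of 2 h and 6 h 0.012 against 0.017. The correlations across genes, which are not independent replicates, were 0.39, 0.30 and 0.26, against 0.50 simulated for each. The simulation drew its noise from the ratios of 2 h over 0 h, the metallothioneins included. Its shared counts thus rest in part on the change being judged and are no independent yardstick. The ratios of 2 h over 0 h also had a smaller SD (0.19) than those of 6 h (0.24) and 12 h (0.35) over 0 h. If part of that wider spread is noise, the simulated counts involving 6 h and 12 h are too low. The simulated correlation of 0.50 follows from the shared array by construction. Part of any shared calls may come from the 0 h array. H3C2 was the only gene past 2-fold in 1 direction at all 3 times, where 1.64 lower genes were simulated. Its calls at 2 h and, at -0.56, at 6 h ended against the mean of the other 3 arrays, which holds the other low H3C2 values.

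Comparisons that do not use the 0 h array gave 23 genes higher and 65 lower for 6 h over 2 h, and 158 higher and 175 lower for 12 h over 6 h. The ER stress and amino acid list was lower at 6 h than at 2 h (median -0.19, 13 of 20 below 0) and higher at 12 h than at 6 h (median 0.70, 18 of 20 above 0), each outside all random lists. Against the mean of the other 3 arrays, 13 genes were 2-fold above and 6 below on the 0 h array, 16 and 4 on the 2 h array, 17 and 33 on the 6 h array, and 132 and 149 on the 12 h array. Of the genes past 2-fold at 12 h with 2 or more probe sets, 73 of 83 higher and 82 of 90 lower genes had 1 sign in all their probe sets (88.0% and 91.1%), a share raised by choosing genes on the median of these probe sets.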

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

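The tests of SLC30A1, of nuclear RNAs and of probe set agreement were set before their results were seen, and the other tests in this part were chosen after. Differences between times could not be tested with 1 array each.

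The metallothionein list had opposite directions at different times, with medians of 1.505 at 2 h, 1.25 at 6 h and -2.56 at 12 h against 0 h. A scaling difference between arrays is argued against by the spike-in RNAs, since the 12 h median less that of the spike-ins was -2.22, and the medians at 2 h and 6 h less the spike-ins were 1.49 and 1.19. How many family members changed stays open, because 10 of 12 probe sets can match several transcripts. Without them, MT1M and MT1G alone had a median of 0.54 at 6 h and -0.30 at 12 h, and neither stood apart, while at 2 h they still did. A candidate explanation is metal-responsive transcription, under which SLC30A1, the zinc exporter gene induced by the same factor, would follow the metallothioneins. It was at 0.23 at 2 h, -0.83 at 6 h and -0.28 at 12 h. At 2 h and 12 h its direction was that of the metallothioneins, but both values fell short of the bound set beforehand for this explanation. At 6 h it went the other way, and that value passed the bound set beforehand against this explanation. The 3 probe sets of SLC30A1 were all lower at 6 h but ran from -2.13 to -0.22, with an SD of 0.97. This spread was not part of the bound, and with 1 gene so uneven the question stays open. Whether the changes came from APRIL or from time in serum-free medium cannot be told apart, because the number of untreated arrays after 0 h was 0.

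Probe sets with no gene name, which enter none of the gene comparisons, were past 2-fold lower in 376 of 11721 cases at 6 h (3.21%) and 253 at 12 h (2.16%), against 0.937% and 1.57% of the probe sets with 1 gene. Only 15 such probe sets were past 2-fold higher at 6 h. Lower RNA integrity at 6 h may contribute, since the 5' less 3' difference fell by over 0.3 in 2 of the 3 control transcripts, ACTB among them at -0.38, but it fell by only 0.05 in GAPDH. At 12 h it fell by over 0.3 in 1 of the 3. A lower share of nuclear RNA was tested with 4 nuclear and 5 cytoplasmic noncoding RNAs, whose medians differed by -0.18 at 6 h, between the bounds set for and against it. At 12 h, for which no bound was set, they differed by -0.69, in the direction of this explanation, with the cytoplasmic median at 0.52 and the nuclear median at -0.17. At 6 h MALAT1 was at -2.09 while TUG1 and MEG3 were at 0.22. Neither explanation is settled, since the transcripts in each test were few and went both ways, and a biological change with time or APRIL was not tested.

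The replication list, with a median of -0.95 at 12 h, was weighed as the largest called group without close paralogs. Noise of single probe sets was examined by sign. Of the list's genes with several probe sets, 78.6% (11 of 14) had 1 sign in all of them, against 42.9% of all genes. This passed the bound set beforehand against noise. Genes far from 0 share 1 sign more often whatever the cause, as did 91.1% of those past 2-fold lower at 12 h. The comparison with all genes therefore cannot decide on noise, though these 11 genes were lower in every probe set. A scaling difference is argued against as the whole cause by the list median less the spike-in median, -0.60. Whether APRIL or further time without serum lies behind it stays open for the reason given above, with 0 untreated later arrays.

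The G2/M list stood apart in opposite directions, at 0.21 at 6 h and -0.27 at 12 h, and this difference was not tested. It does not hold under every setting. Without the probe sets that can match several transcripts, the 6 h median of 0.17 no longer stood apart. Spike-in centring turned the 12 h median to 0.081, because it adds 0.35 to every 12 h ratio. The list's place among random lists stays the same under such a constant. Control probe sets outside the gene comparisons also moved. The spike-in median was -0.35 at 12 h. The 18S ribosomal RNA median was -0.80 at 6 h and -0.95 at 12 h. The 28S ribosomal RNA median was -0.97 at 6 h and -0.48 at 12 h, with 1 of its 3 probe sets in the other direction.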

How the results depend on the processing

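No paired analysis was possible because each time has 1 array. A floor on dim probe sets, its stricter form, the brightest probe set per gene and quantile normalization were not run, since the values are centred per probe set and hold no level. Centring each array on its median changed no count by over 1.5 times and no list call. Alternatives were run on counts, lists and named genes, of which no gene at 2-fold or more changed sign. Of the named-gene values, 214 moved by the yardstick of 0.16 or more and 552 did not. Those that moved numbered 95 with the mean of the other 3 arrays and 63 with spike-in centring. Without probe sets ending in _x_at or _s_at, 16 moved and 94 did not. The rest had no value there, so no change of sign could be seen. Counts below are higher and lower genes. The cause of changed calls was not tested beyond what each setting changes by construction.

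At 1.5-fold the counts were 61 and 68 at 2 h, 227 and 324 at 6 h, 881 and 731 at 12 h, 311 and 410 for 6 h over 2 h, and 694 and 673 for 12 h over 6 h, with 12 genes higher at 2 h and 6 h, 98 higher and 140 lower at 6 h and 12 h. At 3-fold they were 2 and 0, 1 and 7, 33 and 38, 3 and 7, and 27 and 35, with 0, 0 and 3 shared. With the mean of the other 3 arrays as reference they were 16 and 4 at 2 h, 33 lower at 6 h, and 0 higher and 1 lower shared by 6 h and 12 h. The ER stress list at 2 h was then at 0.11 and no longer stood apart, and the replication list at 2 h reversed to 0.22. Another 11 list medians newly stood apart: at 2 h cholesterol synthesis (0.18), fatty acid synthesis (0.19), hypoxia (0.12) and NRF2 (0.25), and at 6 h cholesterol synthesis (0.22), replication (0.27), circadian (-0.12), ER stress (-0.25), immediate-early (-0.31), ERK feedback (-0.17) and NF-kB (-0.09). This reference holds the 12 h array, so a list that is low at 12 h is raised at 2 h and 6 h by arithmetic, and the reverse. Neither of the 2 genes lower at 2 h, H3C2 and LY86, was among the 4 under this reference. At 6 h, 10 of the 20 higher and 22 of the 56 lower genes kept their call. At 12 h, 124 of 187 higher and 135 of 195 lower genes did.

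Without probe sets ending in _x_at or _s_at, 2 genes were higher at 2 h, 2 at 2 h and 6 h, and 8 at 6 h and 12 h. Lists that no longer stood apart were fatty acid synthesis (-0.19) and metallothioneins (-0.30) at 12 h, ER stress (0.14) and replication (-0.12) at 2 h, and G2/M (0.17), hypoxia (-0.18) and metallothioneins (0.54) at 6 h. Of these, replication and hypoxia were not smaller in size than with all probe sets (-0.11 and -0.14). The TGF-beta list at 6 h reversed to 0.031. Lists that newly stood apart were FOXO and starvation at 12 h (0.28) and NRF2 at 2 h (0.19).

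The last settings were chosen after seeing the data. With the probe set of widest range per gene, which favours large changes, counts were 10 lower at 2 h, 87 and 327 at 6 h, 513 and 508 at 12 h, 105 and 353 for 6 h over 2 h, 351 and 278 for 12 h over 6 h, and 44 and 148 shared by 6 h and 12 h. Angiogenic factors (0.24), replication at 2 h (-0.14) and TGF-beta at 6 h (-0.15) no longer stood apart. None of these medians was smaller in size than with the median over probe sets (0.22, -0.11 and -0.13). Spike-in centring gave 12 higher at 6 h, 694 and 76 at 12 h, 15 higher for 6 h over 2 h, 733 and 53 for 12 h over 6 h, and 16 lower shared by 6 h and 12 h. At 12 h it turned the medians of fatty acid synthesis (0.11), G2/M (0.081) and hypoxia (0.059) above 0 by adding 0.35 to every ratio. Their places among random lists do not change under this constant, so these are not lost list calls.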

Other observations

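Single genes, most of them outside the naming rule and chosen after their values were seen, had large ratios, and no list or test stands behind them as a group. SLC7A11, the cystine transporter, was at 0.47, -1.50 and 0.53 at 2, 6 and 12 h, and CTH, which makes cysteine from cystathionine, at 0.53, -1.10 and 0.49, while PHGDH was at 0.29 and DDIT4 at 0.47 at 6 h. At 12 h CYP8B1, the sterol 12-alpha-hydroxylase of bile acid synthesis, was at -1.79, DIO1, the thyroid hormone deiodinase, at -1.89, and LEAP2, a liver-expressed peptide hormone, at -1.87, each on 1 probe set. CYP7A1 was at -0.66 at 2 h, 1.38 at 6 h and -0.05 at 12 h, on 1 probe set. Also at 12 h, IGFBP3 was at 1.65 (SD 0.028 over 2 probe sets), TNFSF10, the death ligand TRAIL, at -1.57 (SD 0.082 over 3), E2F8 at -1.79 and DTL at -1.73 (SD 0.12 over 2).

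Over 41 replication-dependent histone genes, H3C2 and H1-4 among them, the median was -0.02 at 2 h, -0.175 at 6 h and -0.07 at 12 h, with 22, 27 and 27 genes below 0. Of these genes 1, 3 and 4 were past 2-fold lower and 0 higher at each time. The group was chosen after seeing the data and was not set against random lists.

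Probe sets of 1 gene followed each other less at 6 h than at 12 h. Of 354 probe sets past 2-fold lower at 6 h in genes with several, 79 (22.3%) had a median of the gene's other probe sets at or below -0.5, against 238 of 541 (44.0%) at 12 h. This difference was not tested.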
